A study of Danio rerio with 20 samples.

How the data were processed

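The values used were the raw whole-number counts per Ensembl gene that the authors deposited, with 1 table per library. Per the labels, each library came from a pool of 12 to 15 livers dissected from larvae 5 days after fertilization that had been kept at 20 embryos per well, so a replicate is a pool and not a fish. The labels give RNA with an integrity number above 7, 100 ng of total RNA per library, poly(A) selection, 12 cycles of PCR and sequencing on a NextSeq550. Reads were checked with FastQC 0.11.5 and trimmed with Trimmomatic 0.36, against genome build GRCz10. The aligner, the counting tool and the annotation release were not given in the sources used here. The library kit is named both as TruSeq V2 and as NEBNext Ultra II Directional, so whether counting respected the strand is not known.

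Counts covered 32105 gene identifiers in 20 libraries, 5 for each pairing of genotype (wild type or as3mt mutant) and arsenite (0 or 1 mM). Library totals were 28288786 to 39645961 counts in unexposed wild type, 25406597 to 42047561 in exposed wild type, 27505029 to 41248978 in unexposed mutants and 32805944 to 40961344 in exposed mutants. A gene name table gave symbols for 26269 identifiers (81.8%), of which 4144 shared their symbol with another identifier. Symbols are printed as that table gives them, often in the human form with capitals, and an identifier follows where several genes share a symbol. No counts were recorded in any library for 5422 identifiers. No coordinates are given, and gene order around as3mt was taken from a table on a later assembly, GRCz12tu, which is not the build of the counts. That table placed 74.5% of tested genes by symbol and 73.6% of the genotype calls without arsenite.

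Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr with the groups, which left 16389, and scaled by TMM factors. A model with 4 group means was fitted to all 20 libraries by edgeR (estimateDisp, glmQLFit and glmQLFTest, without the robust option), with a common biological coefficient of variation of 0.28. Each comparison was a 2-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called when its adjusted p was under 0.05. The comparisons were arsenite in wild type, arsenite in mutants, genotype without arsenite, genotype with arsenite, and the difference between the arsenite responses (mutant minus wild type). Standard errors of log2 changes were computed as the absolute change divided by the square root of F. CPM used TMM-scaled library sizes, and log2 CPM for components and list means added a prior count of 2. The level of as3mt was also compared by an exact 2-sided permutation test of 5 against 5 libraries. Pearson and Spearman correlations of the arsenite responses ran across genes and have no p.

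A set of 37 gene lists was fixed before the data were examined, together with the comparisons, tests, thresholds, alternatives and the rule for naming genes. The lists cover stress responses, liver metabolism, secreted proteins, large complexes and markers of cell types. The list of secreted liver proteins is one of hepatocyte markers and also holds proteins that are not secreted, such as the enzyme TDO2. Matching ignored case and then a final a or b of paralogue names, and 1560 of 1687 entries were matched. Counts of members up and down were taken over all tested genes and adjusted over the list alone. Lists with at least 5 measured members, 36 of them, were tested with camera from limma at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Camera compares a list with all other genes. With the estimated correlation 4 of 15 calls held for arsenite in wild type and 8 of 18 for arsenite in mutants, and none of 7, 13 and 17 for genotype without arsenite, genotype with it and the difference of the responses.

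Named genes were taken by rule. For each comparison these were as3mt, the 6 largest called changes each way (8 for the difference of the responses) among genes with a mean of at least 10 CPM, a proper symbol and no overlap between the groups of 5, up to 3 called members of each list with the smallest adjusted p, and the 4 smallest adjusted p overall. The rule excluded symbols of clones and placeholders, described as symbols with a colon or in capitals with digits. Since the name table writes ordinary symbols in capitals, that clause was applied only to clone-like and accession-like names, a reading made after the table was seen. Of the genes meeting the rule, those named were chosen for their place in a list, and some are not reported here.

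Alternatives set beforehand were DESeq2 size factors in the edgeR fit, the DESeq2 Wald test, no filter beyond 1 count (26683 genes), a filter at a mean of 10 CPM (6564 genes), robust dispersions, the 20 most abundant genes left out before scaling, the replicate number as a block over all libraries or within genotype, the mean log2 CPM of exocrine pancreas genes as a covariate, a fit of the compared groups alone and each library left out in turn. Chosen after seeing the data were scaling to total counts, thinning all libraries to the smallest total, and leaving out unexposed wild-type replicate 2 together with exposed wild-type replicate 5.

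The depth and the spread of the libraries set what could be called. In counts simulated from the means and dispersions of these libraries, changes of 1.5-fold, 2-fold and 4-fold were recovered in 7.8%, 64.6% and 80% of the changed genes that passed the filter for arsenite in wild type (64, 65 and 65 of 67, 67 and 66), 23.9%, 45.5% and 84.8% for arsenite in mutants, 19.7%, 56.7% and 82.5% for genotype without arsenite, 22.4%, 61.2% and 89.2% for genotype with it, and 7.7%, 32.8% and 76.2% for the difference of the responses, with 3 to 6 false calls among 15932 to 15985 genes. In the other comparisons 63 to 67 changed genes per fold passed the filter. In the simulation, changes of 1.5-fold were therefore often missed. It changed far fewer genes than the real comparisons called, which makes the adjusted threshold stricter. These shares therefore do not carry over to the real comparisons. Replicates of each group differed by more than sampling noise, so no library repeats another. Isoforms, splicing, sequence variants in the reads and the deletion itself were not analysed here.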

Results

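Messenger RNA was sequenced from livers microdissected from zebrafish larvae 5 days after fertilization, each library made from a pool of 12 to 15 livers. The larvae were wild type (TAB5 strain) or homozygous for a CRISPR deletion of 8 bp in exon 3 of as3mt on another wild-type background (ABNYU). The gene encodes arsenite methyltransferase, which adds methyl groups to inorganic arsenic. Larvae of each genotype were kept without arsenite or with 1 mM sodium arsenite from 96 h after fertilization until dissection at about 119 h. Each of the 4 groups held 5 libraries, and totals ran from 25406597 to 42047561 counts per library. The design asks how the liver transcriptome responds to inorganic arsenic and how that response changes without the enzyme. Genotype and strain background differ together, so each difference between genotypes is a difference between these lines.

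The targeted gene, listed as AS3MT, was counted in every library, and an 8 bp deletion leaves most of the transcript countable. Unexposed wild-type libraries held 119 to 134 CPM of it, a read count scaled to library size (mean 125 ± 7.1 SD, n = 5), and unexposed mutant libraries held 61.8 to 81.1 (72.7 ± 9.3 SD, n = 5). Exposed wild-type libraries held 29.8 to 73.6 CPM (45.9 ± 18.4 SD, n = 5) and exposed mutant libraries 8.6 to 18.7 (13.1 ± 4.2 SD, n = 5). No library of 1 genotype overlapped the other genotype at the same exposure. On the log2 scale the transcript fell with arsenite by 1.44 ± 0.22 (SE) in wild type (edgeR adjusted p = 1.81e-05) and by 2.47 ± 0.23 in mutants (edgeR adjusted p = 1.38e-08). Mutants were lower than wild type by a log2 difference of -0.78 ± 0.22 without arsenite (edgeR adjusted p = 0.0213) and of -1.81 ± 0.23 with it (edgeR adjusted p = 9.34e-06). The 2-sided exact permutation p was 0.0079 in each of these 4 comparisons, the smallest that 5 against 5 libraries allow. The difference between the falls, -1.03 ± 0.31, missed the threshold (edgeR adjusted p = 0.0679, and 0.0286 to 0.132 over the alternatives). It passed by DESeq2 (-0.98, adjusted p = 0.0378), with genes under a mean of 10 CPM left out (-1.06, edgeR adjusted p = 0.0286), and without exposed wild-type replicate 1 (0.0412) or 4 (0.0359) or exposed mutant replicate 1 (0.0305). With the replicate number as a block it also passed, over all libraries (edgeR adjusted p = 0.0485) and within genotype (0.0333). Without arsenite, the genotype call was lost when unexposed mutant replicate 2 (edgeR adjusted p = 0.0525) or replicate 4 (0.0536) was left out, and with a covariate for exocrine pancreas transcripts (0.118), within a range of 0.000684 to 0.118 over the alternatives. The log2 difference was then -0.73, -0.74 and -0.70, against -0.78 with all libraries.

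**Figure D1:**
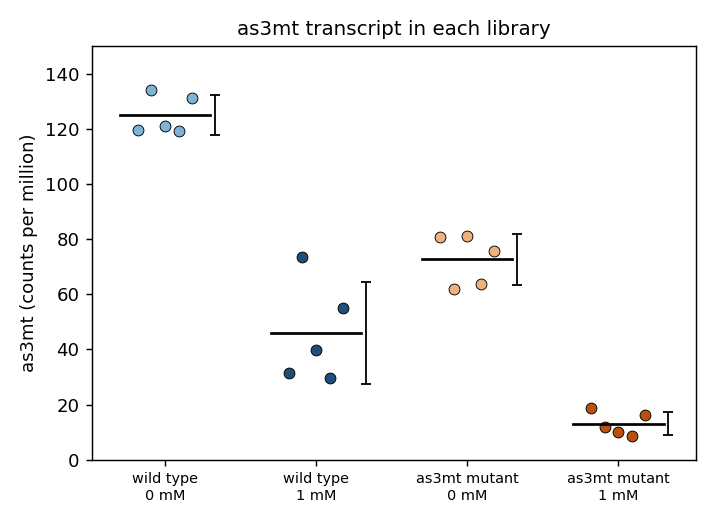
CPM of as3mt in each of the 20 libraries, by genotype and arsenite exposure, with the mean and SD of each group of 5. Group means fall from 125 to 45.9 CPM in wild type and from 72.7 to 13.1 CPM in mutants.

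Exposure separated the libraries more than genotype did. The first principal component of log2 CPM held 54.7% of the variance, with unexposed libraries from -87.6 to -69.1 and exposed ones from 29.6 to 113.5. The second held 15% and separated the genotypes, with mutant libraries from 26.5 to 54.7 and wild-type ones below 0. Unexposed wild-type replicate 2 stood apart at -5.9, against -49.9 to -38.6 for the other unexposed wild-type libraries, and its mean log2 CPM of exocrine pancreas genes was 2.65, against -1.66 to 1.61. Exposed wild-type replicate 5 was the exposed library nearest to the unexposed ones on the first component, at 29.6. The 20 most abundant genes took 31.6% ± 0.58 (SD, n = 5) of counts in unexposed and 22.6% ± 1.94 in exposed wild type, and 30.5% ± 1.03 and 19.2% ± 1.16 in mutants. With library sizes from total counts alone, a scaling chosen after seeing the data, the median log2 change of all tested genes moved to 0.75 for arsenite in wild type, 0.83 for arsenite in mutants, 0.18 for genotype without arsenite and 0.25 for genotype with it. Under the scaling used for the results these 4 medians lay between -0.03 and 0.03, so every direction given here is relative to the bulk of genes.

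**Figure D2:**
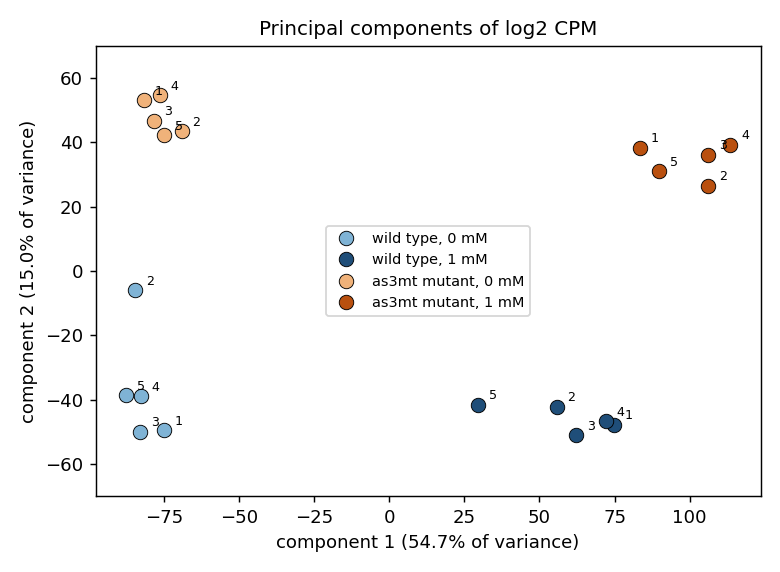
First (54.7% of variance) against second (15%) principal component of log2 CPM, 1 point per library, coloured by group. Exposed libraries lie to the right, and unexposed wild-type replicate 2 lies at -5.9 on the second component, between the genotypes.

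In wild-type livers, arsenite raised transcripts of antioxidant defence, protein folding, protein degradation and cell division and lowered those of secreted liver proteins and of lipid and drug metabolism. With an estimated correlation camera kept its calls only for the lists of Nrf2 targets, heat shock, the proteasome and phase I metabolism (adjusted p = 0.027, 0.027, 0.027 and 0.0295). Transcripts of ptgr1.2, a prostaglandin reductase, went from 2.47 ± 2.44 CPM (SD, n = 5) to 8186 ± 1415 (log2 fold change 11.73 ± 0.65 SE, edgeR adjusted p = 2.8e-11). The ferritin gene fthl28 rose by 10.29 ± 0.50, aifm4 by 8.61 ± 0.26 and SQSTM1, an autophagy receptor, by 6.16 ± 0.41 on the same scale. In the other direction, ahsg1, which encodes a secreted fetuin, went from 552 ± 93.8 CPM to 41.0 ± 18.5 (log2 fold change -3.75 ± 0.26, edgeR adjusted p = 8.39e-10). In all, 8739 of 16389 tested genes passed the edgeR test, 4704 up and 4035 down, or 53.8% up, against 88.1% up when scaled to total counts. Every gene named for this comparison separated the 5 exposed from the 5 unexposed libraries.

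Genes of glutathione and the Nrf2 pathway, the main antioxidant response, rose in wild type. Of 57 measured, 29 rose, 16 fell and 12 did not pass (30 and 17 called when adjusted over the list alone), with a median log2 change of 0.61 (camera adjusted p = 3.14e-08, and adjusted p = 0.027 with an estimated correlation). Glutathione synthetase GSS rose by 4.03 ± 0.18, glutathione reductase GSR by 3.75 ± 0.16 and the glutathione transferase gstp1.2 by 3.00 ± 0.12. Another glutathione transferase, gsto2, an omega-class enzyme of arsenic metabolism, went from 5.76 ± 1.98 to 789 ± 354 CPM (log2 fold change 7.10 ± 0.36, edgeR adjusted p = 8.45e-12). Of 25 genes of arsenic methylation and transport, 12 rose and 8 fell, with the same counts adjusted over the list alone, and the list was not called (median 0.78, camera adjusted p = 0.0854). Outside these lists, the mitochondrial sulfide oxidoreductase SQOR rose by 4.20 ± 0.10, the microsomal transferase mgst3b by 3.75 ± 0.11 and AIFM2, a ubiquinone reductase, by 2.97 ± 0.10, the genes with some of the smallest adjusted p of the comparison (edgeR adjusted p = 5.99e-17, 1.46e-15 and 2.02e-14). Among 21 genes of metal handling, 11 rose and 6 fell, the same adjusted over the list alone, with the metal transporter SLC39A8 up by 5.35 ± 0.44 and the transferrin receptor tfr1a by 2.89 ± 0.28 (list median 0.50, camera adjusted p = 0.275).

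Protein folding and degradation genes rose together in exposed wild type. Of 54 proteasome genes, 52 rose and none fell in the edgeR test, the same adjusted over the list alone, with 2 not passing. Their median was 1.63 (camera adjusted p = 4.74e-45, and adjusted p = 0.027 with an estimated correlation), with PSMB7 up by 2.27 ± 0.11 and PSMB5 by 1.96 ± 0.11. Of 50 heat shock and folding genes, 33 rose and 2 fell, the same adjusted over the list alone. Their median was 0.75 over the list (camera adjusted p = 4.55e-08, and adjusted p = 0.027 with an estimated correlation). The chaperone HSPA4 (ENSDARG00000004754) rose by 2.92 ± 0.16 and the co-chaperone STIP1 by 1.43 ± 0.11. Chaperones of the endoplasmic reticulum and the unfolded protein response did not follow, with 7 of 49 up and 21 down in both counts (median -0.44, or 0.29 scaled to total counts, camera adjusted p = 0.0811). Of 51 autophagy and lysosome genes, 22 rose and 11 fell (23 and 11 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0854).

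Genes of cell division showed a median log2 rise of 2.17 in exposed wild type. Of 71 measured, 66 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 1.07e-21, and adjusted p = 0.189 with an estimated correlation). The mitotic kinase CDK1 rose by 3.46 ± 0.25 and the condensin subunit NCAPD2 by 3.12 ± 0.24. Among 46 genes of the DNA damage response, 22 rose and 9 fell in both counts, without a call for the list (median 0.45, camera adjusted p = 0.0687), and the cell death gene BAX rose by 1.91 ± 0.14. Of 27 interferon genes, 16 rose and 3 fell (18 and 3 adjusted over the list alone), with isg15 up by 5.15 ± 0.81 and a list median of 1.21 (camera adjusted p = 0.15). Exposed replicate 5 did not share the rise of the list, at a mean log2 CPM of -0.42. The other exposed libraries were at 0.97 to 2.45 and the unexposed at -0.36 to 0.20.

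Most of the list of secreted liver proteins, which also holds liver enzymes, fell in exposed wild type. Of 63 measured, 58 fell and 1 rose, the same adjusted over the list alone. Their median was -1.38 (-0.66 scaled to total counts, camera adjusted p = 2.05e-26, and adjusted p = 0.0788 with an estimated correlation). The retinol carrier RBP4 fell by 2.56 ± 0.20. TDO2, an enzyme of the list that degrades tryptophan and is not secreted, fell by 2.24 ± 0.18. Of 44 acute phase and inflammation genes, 22 fell and 6 rose (22 and 7 adjusted over the list alone), including the complement gene c7b (-5.09 ± 0.98, but -2.49 without unexposed wild-type replicate 1). The heme carrier hpxa, in none of the lists, was at -5.13 ± 0.62, or -6.30 without exposed wild-type replicate 5. The acute phase list was not called, with a median of -0.44, or 0.28 scaled to total counts (camera adjusted p = 0.0587). Its mean log2 CPM was 4.62 in unexposed replicate 1 and 3.17 to 3.53 in the other unexposed libraries, against a mean of 3.07 in exposed ones. Of 78 ribosomal protein genes, 76 fell and 1 rose, the same adjusted over the list alone, but their median of -0.64 turned to 0.09 when scaled to total counts (camera adjusted p = 1.17e-20, and adjusted p = 0.284 with an estimated correlation).

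Metabolic genes of wild-type livers fell across several pathways. Of 27 cholesterol synthesis genes, 24 fell and 2 rose, the same adjusted over the list alone, with a median of -2.29 (camera adjusted p = 7.92e-09, and adjusted p = 0.284 with an estimated correlation). Lanosterol synthase LSS fell by 3.40 ± 0.43 and DHCR7, a late enzyme of the pathway, by 2.36 ± 0.27. Of 46 genes of fatty acid oxidation, 37 fell and 4 rose in both counts. Their median was -0.85 over the list (-0.15 scaled to total counts, camera adjusted p = 8.52e-10, and adjusted p = 0.26 with an estimated correlation). Of 43 phase I drug metabolism genes, 26 fell and 3 rose (27 and 3 adjusted over the list alone), with the cytochrome cyp2ad6 down by a log2 change of -2.81 ± 0.21 and a median of -1.14 (-0.43 scaled to total counts, camera adjusted p = 7.82e-10, and adjusted p = 0.0295 with an estimated correlation). Of 44 methionine cycle and one-carbon genes, 26 fell and 9 rose in both counts, but their median of -0.65 turned to 0.06 when scaled to total counts (camera adjusted p = 9.39e-05, and adjusted p = 0.215 with an estimated correlation). GAMT, which methylates guanidinoacetate to creatine, fell by 2.38 ± 0.15, from 6888 ± 803 to 1328 ± 315 CPM, and AHCY, which clears S-adenosylhomocysteine, by 1.33 ± 0.12. The median of 51 glycolysis and gluconeogenesis genes was -0.38 with a mean of 0.03, and 0.35 scaled to total counts (23 down and 11 up in both counts, camera adjusted p = 0.00339, and adjusted p = 0.116 with an estimated correlation). Fatty acid synthesis (20 down and 9 up of 44, 21 and 10 adjusted over the list alone) and bile acid genes (12 down and 2 up of 23 in both counts) had medians of -0.40 and -0.61, which turned to 0.33 and 0.11 scaled to total counts (camera adjusted p = 0.0349 and 0.00604, and adjusted p = 0.348 and 0.281 with an estimated correlation).

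In as3mt mutants arsenite raised transcripts of antioxidant defence, protein folding, protein degradation and cell division and lowered those of secreted liver proteins and of lipid and drug metabolism. The camera calls for cell division and lipid metabolism were lost with an estimated correlation, as in wild type. The chaperone HSP90AA1 went from 0.392 ± 0.325 to 801 ± 205 CPM (log2 fold change 11 ± 0.57 SE, n = 5 per group, edgeR adjusted p = 3.96e-12), and ptgr1.2 rose by 11.56 ± 0.64. The ubiquitin ligase gene mdm2 went from 12.5 ± 1.27 to 118 ± 22.5 CPM (3.24 ± 0.16, edgeR adjusted p = 2.41e-12). Secreted fetuin ahsg1 went from 545 ± 84.5 to 6.0 ± 1.29 CPM (-6.51 ± 0.30, edgeR adjusted p = 7.44e-13), and GAMT from 5121 ± 681 to 352 ± 43.4 CPM (-3.86 ± 0.16, edgeR adjusted p = 2.34e-13). Of 16389 genes, 10132 passed, 5166 up and 4966 down (51% up, against 83.4% scaled to total counts). Each gene named for the mutants separated the 5 exposed from the 5 unexposed libraries.

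In the mutants 30 of 57 glutathione and Nrf2 genes rose and 15 fell, the same adjusted over the list alone. Their median was 0.79 over the list (camera adjusted p = 6.67e-07, and adjusted p = 0.03 with an estimated correlation). Among them, gsto2 rose by 8.21 ± 0.38, PGD, a source of NADPH, by 4.04 ± 0.15 and gstp1.2 by 3.94 ± 0.12, and SQOR rose by 4.43 ± 0.10 outside the list. Proteasome genes rose in 51 of 54 cases with none down in the edgeR test, in both counts (median 2.16, camera adjusted p = 1.5e-45, and adjusted p = 0.03 with an estimated correlation), PSMB7 by 2.64 ± 0.12. Heat shock and folding genes rose in 35 of 50 cases and fell in 5, the same adjusted over the list alone (median 0.90, camera adjusted p = 1.48e-07, and adjusted p = 0.03 with an estimated correlation), HSPA4 (ENSDARG00000004754) by 3.20 ± 0.16. Of 46 DNA damage response genes, 25 rose and 13 fell in both counts (median 0.81, camera adjusted p = 0.0315, and adjusted p = 0.245 with an estimated correlation), with BAX up by 2.62 ± 0.14. Autophagy and lysosome genes rose in 25 and fell in 10 of 51 cases in both counts. Their median was 0.33 over the list (camera adjusted p = 0.0185, and adjusted p = 0.507 with an estimated correlation). Cell division genes rose in 51 of 71 cases and fell in 6 (52 and 6 adjusted over the list alone), CDK1 by 3.15 ± 0.25, with a median of 1.57 (camera adjusted p = 6.27e-09, and adjusted p = 0.499 with an estimated correlation).

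Liver-specific transcripts of the mutants fell with arsenite. Of 63 genes in the secreted protein list, 58 fell and 1 rose (59 and 1 adjusted over the list alone), with a median of -2.15 (-1.33 scaled to total counts, camera adjusted p = 1.17e-33, and adjusted p = 0.03 with an estimated correlation). The apolipoprotein apom fell by 3.40 ± 0.18, the fibrinogen chain FGG by 2.44 ± 0.14 and the amino acid transporter SLC43A1 (ENSDARG00000037748), outside the list, was at -7.22 ± 0.44. The alcohol dehydrogenase adh8a fell by 6.69 ± 0.51 and cbln8 by 6.94 ± 0.81. Phase I genes fell in 33 of 43 cases and rose in 4 in both counts (median -1.45, -0.62 scaled to total counts, camera adjusted p = 8.6e-10, and adjusted p = 0.03 with an estimated correlation), with cyp2aa12 at -3.94 ± 0.21 and cyp2n13 at -3.55 ± 0.19. Phase II conjugation genes fell in 32 and rose in 8 of 53 cases in both counts. Their median was -1.07 over the list (-0.22 scaled to total counts, camera adjusted p = 0.0315, and adjusted p = 0.638 with an estimated correlation). Glycolysis and gluconeogenesis genes fell in 27 and rose in 12 of 51 cases (28 and 12 adjusted over the list alone), and their median of -0.61 turned to 0.22 scaled to total counts (camera adjusted p = 0.000268, and adjusted p = 0.03 with an estimated correlation). Methionine cycle and one-carbon genes fell in 25 and rose in 8 of 44 cases (26 and 8 adjusted over the list alone), with CSAD, an enzyme of taurine synthesis, down at -4.26 ± 0.28. Their median was -0.88 over the list (-0.06 scaled to total counts, camera adjusted p = 9.83e-06, and adjusted p = 0.139 with an estimated correlation).

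Cholesterol synthesis genes fell in 21 of 27 cases in the mutants and rose in 2, in both counts. Their median was -1.54 over the list (-0.72 scaled to total counts, camera adjusted p = 0.00152, and adjusted p = 0.594 with an estimated correlation). Fatty acid oxidation genes fell in 37 of 46 cases and rose in 4, in both counts. Their median was -0.95 over the list (-0.12 scaled to total counts, camera adjusted p = 9.86e-08, and adjusted p = 0.317 with an estimated correlation). Bile acid genes fell in 14 of 23 cases and rose in 2, in both counts. Their median was -0.98 over the list (-0.16 scaled to total counts, camera adjusted p = 0.00121, and adjusted p = 0.221 with an estimated correlation). For 44 fatty acid synthesis genes, 24 down and 10 up in both counts, the median of -0.54 turned to 0.28 scaled to total counts (camera adjusted p = 0.00833, and adjusted p = 0.282 with an estimated correlation). Ribosomal protein genes fell in 77 of 78 cases and rose in 1, in both counts, but their median of -0.64 turned to 0.20 scaled to total counts (camera adjusted p = 1.91e-12, and adjusted p = 0.507 with an estimated correlation). Markers of endothelium fell in 19 of 25 cases and rose in 1, in both counts, with the vessel receptor kdrl down at -1.71 ± 0.10. Their median was -0.98 over the list (-0.14 scaled to total counts, camera adjusted p = 8.66e-07, and adjusted p = 0.0466 with an estimated correlation). Stellate cell and fibroblast markers fell in 20 of 31 cases and rose in 1, in both counts, with the fibronectin FN1 (ENSDARG00000006526) down at -3.65 ± 0.20. Their median was -0.98 over the list (-0.14 scaled to total counts, camera adjusted p = 3.93e-05, and adjusted p = 0.03 with an estimated correlation).

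**Figure D3:**
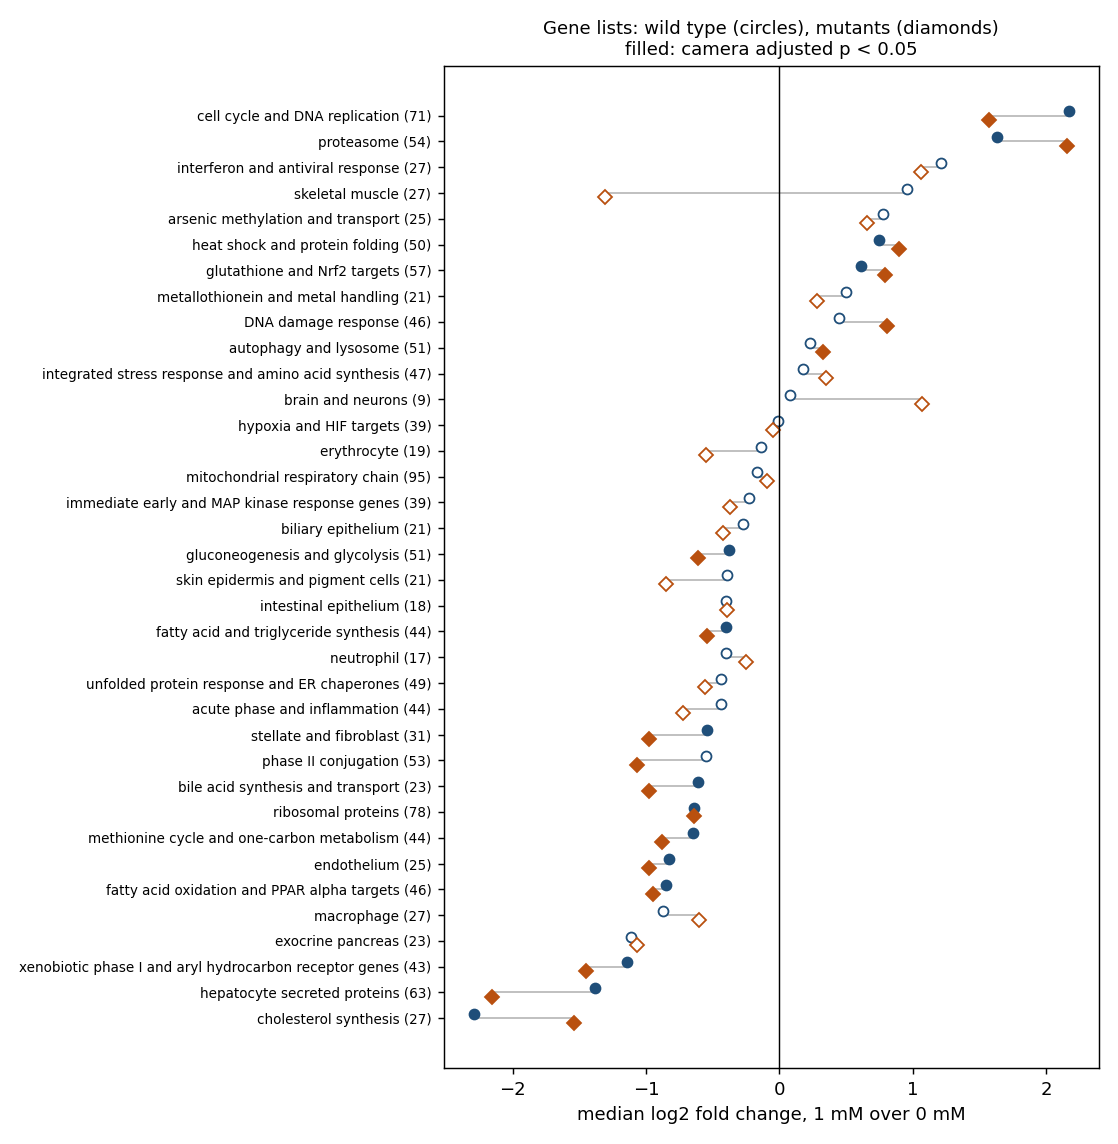
Median log2 change with arsenite of each gene list in wild type (circles) and as3mt mutants (diamonds), filled where camera called the list with its preset correlation. Scaled to total counts, the called medians of the one-carbon, fatty acid synthesis, glycolysis, bile acid, ribosomal and stellate lists in wild type and of the fatty acid synthesis, glycolysis and ribosomal lists in mutants turn from below 0 to above it.

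The arsenite responses of the genotypes ran alike across genes, with a Pearson r of 0.874 and a Spearman rho of 0.871 between their log2 changes over 16389 genes, which are not independent replicates. Of 7609 genes called in both, 7591 (99.8%) moved the same way, and 5548 of these (73.1%) changed more in the mutants. The test of the difference itself called 652 genes, 214 with a more positive and 438 with a more negative response in mutants. Among these, 328 fell in both genotypes and more in mutants, and 137 rose in both and more in mutants. A further 77 fell and 60 rose with a call in mutants alone, 11 fell and 19 rose with a call in wild type alone, 16 moved in opposite directions and 4 rose in both but less in mutants.

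Genes with a more negative response in mutants included 21 of 63 in the list of secreted liver proteins and some for metabolic enzymes. The difference between the log2 changes was -2.76 ± 0.34 (SE, n = 5 per group, edgeR adjusted p = 0.000162) for ahsg1, -1.2 ± 0.16 for the clotting factor F9 and -3.34 ± 0.58 for the apolipoprotein apobb.2. Adjusted over the list alone, 41 genes of the secreted protein list were more negative and 1 more positive, and the median difference was -0.68 (camera adjusted p = 4.11e-24, and adjusted p = 0.206 with an estimated correlation). In one-carbon metabolism 6 of 44 genes were more negative and 1 more positive (10 and 1 adjusted over the list alone), including GAMT at -1.49 ± 0.20 and the glycine decarboxylase GLDC at -1.57 ± 0.27, while the methionine adenosyltransferase mat2al differed by 1.39 ± 0.33. Their median was -0.36 over the list (camera adjusted p = 0.000351, and adjusted p = 0.383 with an estimated correlation). Phase I genes had 4 of 43 more negative in both counts, cyp2aa12 at -1.82 ± 0.27. Their median was -0.44 over the list (camera adjusted p = 0.000154, and adjusted p = 0.346 with an estimated correlation). Glycolysis and gluconeogenesis genes had 5 of 51 more negative and 3 more positive (18 and 3 adjusted over the list alone) and a median of -0.44 (camera adjusted p = 0.00115, and adjusted p = 0.206 with an estimated correlation). Other genes with a more negative response were the carbonyl reductase CBR1 (-1.69 ± 0.20), ENOSF1 (-1.56 ± 0.19), the transporter SLC16A12 (ENSDARG00000017773; -3.34 ± 0.43), adh8a (-3.10 ± 0.60), the glutathione peroxidase gpx4a (-1.60 ± 0.30), the aquaglyceroporin aqp9b (-1.55 ± 0.26) and ifit16 (-3.01 ± 0.42).

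Genes with a more positive response in mutants included mdm2 and 14 of 54 for the proteasome. The difference was 1.77 ± 0.21 for mdm2 (edgeR adjusted p = 0.000162), and exposed mutants held 118 ± 22.5 CPM of mdm2 against 41.7 ± 9.08 in exposed wild type. Only 4 of 46 DNA damage response genes differed, all with a more positive response (7 with 3 the other way adjusted over the list alone), and the list was not called (median 0.07, camera adjusted p = 0.08). Of 54 proteasome genes, 14 responded more positively and none more negatively in the edgeR test (33 and none adjusted over the list alone), with PSMD10 at 1.06 ± 0.20 and PSMD8 at 0.74 ± 0.14. Their median was 0.44 over the list (camera adjusted p = 7.49e-16, and adjusted p = 0.383 with an estimated correlation). Part of this is a lower start, as the median of mutants against wild type was -0.20 without arsenite and 0.21 with it. That lower start depends on the scaling, since scaled to total counts these medians were -0.03 and 0.49. PSMD8, and CIAPIN1 below, were also lower in unexposed mutants, by about as much as their responses differed. The stress gene nupr1a differed by 1.84 ± 0.23, RNF14 (ENSDARG00000078683) by 1.93 ± 0.38, the iron-sulfur assembly factor CIAPIN1 by 1.33 ± 0.14 and gstp1.2 by 0.93 ± 0.15. Cell division genes had 3 of 71 more negative (10 adjusted over the list alone), among them MCM6 (ENSDARG00000057683) at -1.12 ± 0.25. Their median was -0.52 over the list (camera adjusted p = 0.000154, and adjusted p = 0.782 with an estimated correlation). Against wild type, the median of the cell division list in mutants was 0.24 without arsenite and -0.22 with it. For cholesterol synthesis 0 of 27 genes passed the edgeR test in either count, 7 were more positive at an unadjusted p under 0.05 and 3 by DESeq2, with a median of 0.83 (camera adjusted p = 0.000294, and adjusted p = 0.696 with an estimated correlation). Here too the median of mutants against wild type was lower at the start, at -0.47 without arsenite and 0.32 with it. Camera called the list in neither (adjusted p = 0.137 and 0.153). The positive share of the 652 genes, 32.8%, was 53.9% scaled to total counts and 45.3% of 1137 genes by DESeq2. The count dropped to 383 without exposed mutant replicate 3, 405 without exposed mutant replicate 4 and 408 without exposed wild-type replicate 2. With the replicate number as a block within genotype it was 901, with 573 of the 652 among them.

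**Figure D4:**
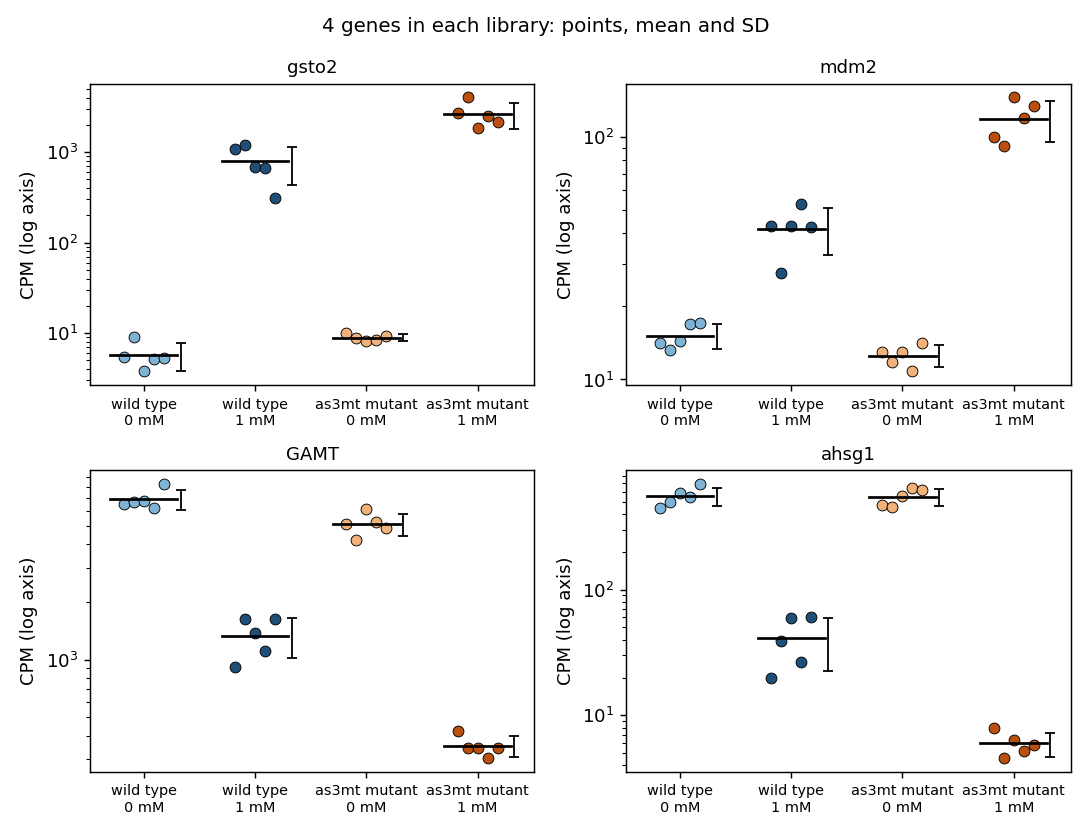
CPM on a log axis of gsto2, mdm2, GAMT and ahsg1 in each of the 20 libraries, with group means and SDs. In exposed mutants, mdm2 averages 118 CPM against 41.7 in exposed wild type, and ahsg1 6.0 against 41.0.

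Without arsenite, the mutant line differed from wild type in fewer genes than the exposure changed. The C-reactive protein gene crp5 went from 3776 ± 600 CPM in wild type to 278 ± 80.2 in mutants (SD, n = 5 per group, log2 difference -3.77 ± 0.28 SE, edgeR adjusted p = 2.51e-08) and crp3 was lower at -1.84 ± 0.32. The immunophilin gene fkbp16 went from 93.0 ± 49.1 CPM to 0.0732 ± 0.0526, which rests on 10 counts in the 5 mutant libraries together (-10.28 ± 0.59, edgeR adjusted p = 5.25e-10). Also lower were MTSS2 (ENSDARG00000028943; -3.30 ± 0.44), the mitochondrial channel VDAC1 (-2.95 ± 0.23), pemt, which methylates phosphatidylethanolamine (-2.65 ± 0.27), acss2l (-2.30 ± 0.43) and CIAPIN1 (-1.51 ± 0.10). Higher in mutants were ptgfrna (2.14 ± 0.28), SMIM14 (2.07 ± 0.26), the lipoate synthase LIAS (1.36 ± 0.09, edgeR adjusted p = 6.34e-09), and the antigen presentation genes b2m (2.92 ± 0.71) and mhc1zba (1.32 ± 0.20). In all 2265 of 16389 genes differed, 968 higher and 1297 lower in mutants, or 42.7% higher, against 74.1% scaled to total counts. Apart from ctrl, the genes named for this comparison separated all 5 mutant from all 5 wild-type libraries.

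Several large complexes were lower in unexposed mutants by small amounts. Of 78 ribosomal protein genes, 50 were lower and none higher by edgeR (70 and 1 adjusted over the list alone), with a median of -0.29, or -0.12 scaled to total counts, and RPLP1 at -0.42 ± 0.08 (camera adjusted p = 3.4e-14, and adjusted p = 0.888 with an estimated correlation). Of 95 respiratory chain genes, 47 were lower and 4 higher (70 and 5 adjusted over the list alone), among them NDUFS7 at -0.72 ± 0.12 and NDUFB1 at -0.71 ± 0.12. Their median was -0.36 over the list, or -0.19 scaled to total counts (camera adjusted p = 5.19e-13, and adjusted p = 0.888 with an estimated correlation). Genes of the unfolded protein response were lower in 17 of 49 cases, with none higher in the edgeR test (21 and none adjusted over the list alone), and the median was -0.50, or -0.33 scaled to total counts (camera adjusted p = 1.43e-07, and adjusted p = 0.888 with an estimated correlation). The translocon subunit SEC61G was lower at -1.37 ± 0.20, the stress sensor atf6 at -0.85 ± 0.14 and the disulfide isomerase P4HB at -0.61 ± 0.15. Proteasome genes were lower in 13 of 54 cases, with none higher by edgeR (16 and none adjusted over the list alone), PSMD8 at -0.70 ± 0.10. Their median was -0.20 over the list, or -0.03 scaled to total counts (camera adjusted p = 0.00129, and adjusted p = 0.888 with an estimated correlation). Of 71 cell division genes 0 passed the edgeR test in either count, 10 were higher and 1 lower at an unadjusted p under 0.05 and 1 was higher by DESeq2, with a median of 0.24 (camera adjusted p = 0.0302, and adjusted p = 0.888 with an estimated correlation). Stellate cell markers had 4 of 31 higher in both counts, with the collagen COL6A2 at 0.98 ± 0.21. Their median was 0.27 over the list (camera adjusted p = 0.0356, and adjusted p = 0.888 with an estimated correlation), a call also lost with the pancreas covariate (camera adjusted p = 0.202) and with the replicate block (0.0509).

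Hepatocyte transcripts of unexposed livers differed little by genotype. Of 63 genes in the secreted protein list, 6 were lower and 1 higher in mutants, the same adjusted over the list alone, and the list was not called (median -0.12, or 0.06 scaled to total counts, camera adjusted p = 0.183). The hepatocyte fatty acid carrier fabp10a held 21200.0 ± 2869 CPM in wild type and 15050.0 ± 1222 in mutants (log2 difference -0.49 ± 0.13, edgeR adjusted p = 0.0152), a call lost without unexposed wild-type replicate 1 (edgeR adjusted p = 0.0533, log2 difference -0.42) and with the pancreas covariate (0.131, log2 difference -0.41), within 0.00392 to 0.131 over the alternatives.

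Digestive enzymes of the exocrine pancreas, an organ that lies against the liver, were higher in the mutant pools. Of 23 measured, 2 were called higher over all genes and 16 adjusted over the list alone, with none lower in either count and a median of 2.72 (camera adjusted p = 1.46e-05, and adjusted p = 0.888 with an estimated correlation). The mean log2 CPM of these genes was 2.83 ± 1.43 (SD, n = 5) in unexposed mutants and 1.90 ± 1.96 in exposed mutants, against 0.17 ± 1.94 and 0.20 ± 1.2 in wild type. The chymotrypsinogen ctrb.2 held 29.1 ± 30.7 CPM in unexposed mutants and 4.95 ± 5.09 in wild type (log2 difference 2.56 ± 0.80, edgeR adjusted p = 0.0377), and ctrl differed by 3.21 ± 1.05 (edgeR adjusted p = 0.0464, above all wild-type libraries in 4 of 5). The ctrb.2 call was lost without unexposed mutant replicate 1 (edgeR adjusted p = 0.16, log2 difference 1.64) or unexposed wild-type replicate 1 (0.095), 3 (0.0911) or 4 (0.074), with robust dispersion (0.0642), with the replicate number as a block (0.0606) and with only the 2 groups compared (0.0501), within 0.0159 to 0.16 over the alternatives. The ctrl call was lost without unexposed mutant replicate 1 (edgeR adjusted p = 0.172, log2 difference 2.16), 2 (0.0556) or 4 (0.0598) or unexposed wild-type replicate 1 (0.107), 3 (0.0987), 4 (0.0842) or 5 (0.0542), with robust dispersion (0.0762) and with the replicate number as a block (0.0852), within 0.029 to 0.31. With the mean of these pancreas genes as a covariate, 970 genes differed by genotype instead of 2265. The calls of b2m and P4HB then ended (edgeR adjusted p = 0.0805 and 0.0702, the highest over their alternatives, which began at 0.000333 and 0.00122), as did those of as3mt, fabp10a, ctrb.2 and ctrl. The log2 difference was 2.48 for b2m and -0.55 for P4HB with the covariate, against 2.92 and -0.61 without, and 0.79 for ctrb.2 and 0.57 for ctrl.

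In exposed livers the genotypes differed in 3369 genes, 1259 higher and 2110 lower in mutants (37.4% higher, against 78.5% of 5470 scaled to total counts). The omega glutathione transferase gsto1 held 16.9 ± 2.39 CPM in exposed wild type and 99.1 ± 24.1 in exposed mutants (SD, n = 5 per group, log2 difference 2.55 ± 0.39 SE, edgeR adjusted p = 7.53e-05). Higher in mutants were also slc2a9l1 (3.72 ± 0.34), the transcription factor ZBTB16 (2.58 ± 0.28), the complement gene c3a.4 (2.12 ± 0.32), ifi30a (1.96 ± 0.26), the phospholipase PLA2G12A (1.94 ± 0.12) and mdm2 (1.5 ± 0.15). Lower in mutants were fkbp16 (-8.73 ± 0.53), crp3 (-4.29 ± 0.35), crp5 (-4.09 ± 0.28), SLC16A12 (ENSDARG00000017773; -3.39 ± 0.33), gpx4a (-2.08 ± 0.22) and FAHD1 (-1.89 ± 0.13, edgeR adjusted p = 3.76e-09). All of these separated the 5 mutant from the 5 wild-type libraries.

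The list of secreted liver proteins was the one that set exposed mutants most apart from exposed wild type by camera p at the preset correlation. Of 63 measured, 50 were lower and none higher by edgeR (53 and 1 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 7.96e-26, and adjusted p = 0.251 with an estimated correlation). Lower members included ahsg1 (-2.77 ± 0.26), F9 (-1.57 ± 0.12) and the fibrinogen chain fga (-1.4 ± 0.17). Of 44 one-carbon genes, 18 were lower and 2 higher (22 and 2 adjusted over the list alone), GAMT at -1.91 ± 0.15 and CSAD at -2.49 ± 0.26. Their median was -0.40 over the list (-0.11 scaled to total counts, camera adjusted p = 1.07e-06, and adjusted p = 0.251 with an estimated correlation). Of 49 unfolded protein response genes, 26 were lower and 1 higher (31 and 1 adjusted over the list alone), P4HB at -1.28 ± 0.15 and SEC61G at -1.38 ± 0.20. Their median was -0.68 over the list (camera adjusted p = 5.03e-08, and adjusted p = 0.604 with an estimated correlation). Glycolysis and gluconeogenesis genes were lower in 21 of 51 cases and higher in 2 (24 and 2 adjusted over the list alone). Their median was -0.46 over the list (-0.18 scaled to total counts, camera adjusted p = 2.91e-06, and adjusted p = 0.0551 with an estimated correlation). Phase I genes were lower in 17 of 43 cases and higher in 4 (21 and 5 adjusted over the list alone), cyp2ad6 at -2.39 ± 0.21. Their median was -0.46 over the list (-0.20 scaled to total counts, camera adjusted p = 2.74e-05, and adjusted p = 0.251 with an estimated correlation). Bile acid genes were lower in 8 of 23 cases (12 adjusted over the list alone), with none higher by edgeR. Their median was -0.53 over the list (-0.26 scaled to total counts, camera adjusted p = 0.00143, and adjusted p = 0.399 with an estimated correlation). Endothelial markers were lower in 10 of 25 cases (12 adjusted over the list alone), with none higher by edgeR. Their median was -0.38 over the list (-0.09 scaled to total counts, camera adjusted p = 0.00213, and adjusted p = 0.399 with an estimated correlation).

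Ribosomal protein genes of exposed livers were lower in mutants in 65 of 78 cases and higher in 1 (74 and 2 adjusted over the list alone), with a median of -0.30, or -0.01 scaled to total counts (camera adjusted p = 3.1e-09, and adjusted p = 0.755 with an estimated correlation). Respiratory chain genes were lower in 34 of 95 cases and higher in 2 (42 and 2 adjusted over the list alone), and their median of -0.28 turned to 0.01 scaled to total counts (camera adjusted p = 5.18e-05, and adjusted p = 0.792 with an estimated correlation). Phase II genes (19 lower and 4 higher of 53, 19 and 5 adjusted over the list alone) and fatty acid synthesis genes (13 lower and 3 higher of 44, 16 and 4 adjusted over the list alone) had medians of -0.16 and -0.27, which turned to 0.13 and 0.01 scaled to total counts (camera adjusted p = 0.00213 and 0.00373, and adjusted p = 0.755 and 0.399 with an estimated correlation). Proteasome genes were higher in mutants in 11 of 54 cases (12 adjusted over the list alone), with none lower by edgeR, PSMC6 by 0.40 ± 0.09. Their median was 0.21 over the list (camera adjusted p = 0.000133, and adjusted p = 0.762 with an estimated correlation). Of 46 DNA damage response genes, 10 were higher and 4 lower (10 and 6 adjusted over the list alone) with a median of -0.11, a mean of 0.04 and no call (camera direction up, adjusted p = 0.203).

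Exocrine pancreas genes were also higher in exposed mutant pools, 6 of 23 over all genes and 16 adjusted over the list alone, with none lower in either count. Their median was 2.95 over the list (camera adjusted p = 0.00143, and adjusted p = 0.781 with an estimated correlation). Of these, ctrb.2 differed by 3.16 ± 0.84 (edgeR adjusted p = 0.0103) and prss1, a trypsinogen, by 2.66 ± 0.81 (edgeR adjusted p = 0.0228), each above all exposed wild-type libraries in 4 of 5 mutant libraries. The prss1 call was lost without exposed mutant replicate 1 (edgeR adjusted p = 0.11, log2 difference 1.73), exposed wild-type replicate 2 (0.0581) or exposed wild-type replicate 4 (0.0525), and with the pancreas covariate (0.148), within 0.00666 to 0.148 over the alternatives.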

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

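Chosen only after the result was seen were the tests of a mutant library under a wild-type label, of pancreas tissue in a single pool, of a part of the mutant line's background, of the choice of scaling, of any single library and of linkage as the cause of most calls for the genotype differences, and of the pancreas read from fold changes. The level of as3mt and the wider marker set used for a mixture were not in its prediction written beforehand.

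Of 63 genes in the list of secreted liver proteins 21 responded more negatively to arsenite in as3mt mutants than in wild type, and of 54 proteasome genes 14 more positively. These results stand here because the test of the difference between the responses passed its threshold, for 652 genes in all. The difference in log2 change was -2.76 for ahsg1, -3.34 for apobb.2, -1.2 for F9, -1.49 for GAMT, -1.57 for GLDC, -1.82 for cyp2aa12, -3.10 for adh8a, -1.69 for CBR1, -1.56 for ENOSF1, -1.60 for gpx4a, -1.55 for aqp9b, -3.34 for SLC16A12 (ENSDARG00000017773), -3.01 for ifit16, -1.54 for FN1 (ENSDARG00000006526) and -1.12 for MCM6 (ENSDARG00000057683). On the positive side it was 1.77 for mdm2, 1.84 for nupr1a, 1.93 for RNF14 (ENSDARG00000078683), 1.39 for mat2al, 1.33 for CIAPIN1, 1.06 for PSMD10, 0.74 for PSMD8 and 0.93 for gstp1.2. The complement gene c3a.4 differed by 1.72 (edgeR adjusted p = 0.0339, and 0.00275 to 0.0678 over the alternatives). That call was lost without unexposed wild-type replicate 1 (0.0678), exposed wild-type replicate 2 (0.0663), exposed mutant replicate 4 (0.0655) or 3 (0.0589), or unexposed mutant replicate 3 (0.0628), 5 (0.0604) or 1 (0.0525). BAX differed by 0.71 (edgeR adjusted p = 0.037, and 0.00874 to 0.0759 over the alternatives), and its call was kept among the libraries left out in turn only without unexposed wild-type replicate 2, exposed wild-type replicate 4, unexposed mutant replicate 5 or exposed mutant replicates 1 and 2. It was also lost with no filter (0.0573), with the pancreas covariate (0.0588) and after thinning (0.0601). The 652 dropped to 383, 405 and 408 without exposed mutant replicate 3, exposed mutant replicate 4 and exposed wild-type replicate 2.

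Among gene lists, camera called a more negative response in mutants for secreted liver proteins (median difference -0.68), cell cycle (-0.52), stellate and fibroblast markers (-0.49), phase I metabolism (-0.44), glycolysis and gluconeogenesis (-0.44), bile acids (-0.43), one-carbon metabolism (-0.36), phase II conjugation (-0.34), endothelium (-0.30) and fatty acid synthesis (-0.23). It called a more positive one for cholesterol synthesis (0.83), macrophage markers (0.53), the proteasome (0.44), glutathione and Nrf2 targets (0.19), heat shock (0.16), autophagy (0.16) and the respiratory chain (0.07). None of these 17 calls held with an estimated correlation, where camera adjusted p ran from 0.142 to 0.948. The call of the respiratory chain was also lost with the pancreas covariate (camera adjusted p = 0.113). Some of these differences partly reflect genotype differences present without arsenite. The median of mutants against wild type was -0.47 without arsenite and 0.32 with it for cholesterol synthesis. It was 0.24 and -0.22 for cell cycle, 0.27 and -0.19 for stellate markers, and -0.20 and 0.21 for the proteasome. For secreted liver proteins it was -0.12 and -0.78.

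Several libraries stood far from the other 4 of their group, by a gap of more than 0.71 of the group's range. Of 220 groups of values examined 10 did so, and chance alone gives about 1 in 20. GAMT was at 8280 CPM in unexposed wild-type replicate 5 against 6230 to 6760 in the others. In unexposed mutant replicate 1 the pancreas genes ctrb.2 and prss1 were at 83.7 and 274 CPM, against at most 20.6 and 63.1 in the others. Mean log2 CPM was 4.62 for acute phase genes in unexposed wild-type replicate 1 (others 3.17 to 3.53), 2.92 for skin genes in unexposed wild-type replicate 4 (0.76 to 1.26), 4.13 for cholesterol synthesis in exposed wild-type replicate 1 (4.89 to 5.20), 2.75 for skeletal muscle in exposed wild-type replicate 3 (-0.89 to 0.05), 4.58 for arsenic methylation and transport in exposed mutant replicate 4 (4.72 to 4.77) and 2.52 for erythrocyte genes in exposed mutant replicate 5 (2.16 to 2.26). On the second principal component unexposed wild-type replicate 2 was at -5.9 against -49.9 to -38.6.

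Unexposed wild-type replicate 2 lay between the genotypes. Its position was taken over 14 genes that differed by more than 3 log2 units between exposed genotypes, and the same way by more than 2 between unexposed ones. The median was 0.40 of the way to the mutants (interquartile range 0.24), and 0.46 (0.26) over the 11 genes outside the pancreas list. A mutant library under a wild-type label is argued against by as3mt, at 134.1 CPM against at most 81.1 in unexposed mutants. A mixture with mutant-line livers predicted an even position, with an interquartile range under 0.3. The 14 and the 11 genes met this. Over 29 genes past 2 log2 units in exposed livers, without the pancreas list, the range was 0.34. That missed the prediction but stayed under the limit set beforehand against a mixture. The elastase gene CELA1 (ENSDARG00000017314), not matched to that list, stayed among the 11 and the 29. In the other unexposed libraries the range over the 14 genes was 0.16 to 4.3, so evenness alone cannot tell a mixture from another pool. A mixture would also have put as3mt at 102.6 CPM (SD of the groups at most 9.3). Neither the 29 genes nor this level of as3mt was part of the prediction written beforehand. Pancreas tissue predicted a shift of 3.9 ± 2.6 (SE) of the 38.3 units by which the library was displaced, over the other 19 libraries. Fish carrying part of the mutant line's background without the deletion may explain the position of 0.40, with the same doubt from 0.34, and stay open, as does any other difference between pools.

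The 2265 genotype differences without arsenite may come from the as3mt mutation, from strain background or from what was dissected, and the first and second are confounded by the design. Unexposed wild-type replicate 2 as their source is argued against by 2802 calls without it, and any other single unexposed library by 1637, the lowest count with 1 left out. By gene order in assembly GRCz12tu, with 73.6% of calls placed, 2.8% of the placed calls lay among the nearest 100 tested genes on each side of as3mt. Of all calls 71.5% were placed elsewhere, so that window does not hold most of them, wherever the unplaced ones lie. As 200 genes could not hold most of the calls, this was fixed in advance, and linkage over a longer stretch stays open. Among placed genes, those near as3mt were called more often (47 of 200 genes against 1620 of 12017, odds ratio 1.97, 95% interval 1.38 to 2.76, 2-sided Fisher's exact p = 0.000154). That odds ratio fell just short of the one set beforehand for this explanation. With the pancreas covariate 970 genes were called, as that explanation predicts, but the covariate itself differs between genotypes and takes up part of any genotype effect. Its fold changes followed those without it with a slope of 0.96, the median absolute log2 change going from 0.84 to 0.78 and the SE from 0.20 to 0.23, which argues against pancreas tissue as the whole cause.

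Of the genes called in both genotypes 73.1% changed more in mutants. A weak response of exposed wild-type replicate 5 is argued against by 69% without it, the choice of scaling by at least 72.8% over the other scalings, and unequal depth by 73.8% after thinning. A larger response without the methyltransferase and a different sensitivity of the ABNYU background both stay open as untested, and mutants beside wild-type siblings of 1 background would separate them.

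Libraries were also regrouped at random, with 100 splits per comparison, the real one included. The real groups alone gave as many calls for arsenite in wild type (8739, highest other 3197), arsenite in mutants (10132, highest other 2222), genotype without arsenite (2265, highest other 293) and genotype with it (3369, highest other 588), 1 of 100 in each case. That is the smallest share 100 splits can give. The other splits mixed the compared conditions in both groups, and the median of their calls was 0. For the difference of the responses 2 of 100 splits gave as many as 652 genes. These splits exchanged genotypes within each exposure, so they tested for no genotype effect at all and not the difference of responses alone. Chance is therefore not excluded by them for that difference. The other split, with 1802 calls, points to a structure of the samples. Its exchange of 5 unexposed and 1 exposed library turns the difference of responses largely into the mean genotype difference.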

How the results depend on the processing

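Tests chosen only after the result was seen were scaling to total counts, thinning, leaving out 2 wild-type libraries together and the ranges for the similarity of the responses.

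Of 133 named gene results, 123 kept their direction and their side of the threshold under every alternative in which the gene was tested. Another 10 crossed the threshold under at least 1. None reversed. Not every gene was tested under each alternative. With the filter at a mean of 10 CPM, 22 of the 25 results for genotype without arsenite were tested. The 10 were ctrb.2, ctrl, prss1, as3mt, fabp10a, b2m and P4HB in the genotype comparisons and as3mt, BAX and c3a.4 in the difference of the responses.

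A filter at a mean of 10 CPM gave 4601 calls for arsenite in wild type, 5066 in mutants, 1107 for genotype without arsenite and 1987 with it, where 6564 instead of 16389 genes were tested, and a correlation of 0.945 between the responses. The exocrine pancreas covariate lowered the calls for genotype without arsenite from 2265 to 970, a covariate that itself differs between the genotypes. Scaling to total counts raised those for genotype with arsenite from 3369 to 5470, and DESeq2 raised the difference of the responses from 652 to 1137 genes. The cause was not tested for these. Scaling to total counts also reversed 387 of the genes called under both scalings for arsenite in wild type and 575 in mutants, which follows from its shift of all genes. With an estimated correlation camera called 4, 8, 0, 0 and 0 lists instead of 15, 18, 7, 13 and 17.

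Leaving out each library in turn gave 8119 to 8816 calls for arsenite in wild type, 9669 to 9911 in mutants, 1637 to 2802 for genotype without arsenite, 2658 to 3243 with it and 383 to 793 for the difference of the responses, with correlations between the responses of 0.854 to 0.875. Without exposed mutant replicate 3, exposed mutant replicate 4 or exposed wild-type replicate 2 the difference of the responses dropped to 383, 405 or 408 genes.

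After centring each group, same-numbered libraries correlated by 0.02 to 0.2 (mean 0.13) between the wild-type groups, 0.05 to 0.19 (0.14) between the mutant groups and -0.08 to 0.4 (0.18) between the exposed groups, against means of -0.03, -0.04 and -0.04 for other numbers. In the other 3 pairs of groups the means were 0.1, 0.06 and -0.02, with 2, 2 and 0 of 5 over 0.1. Correlations passed 0.1 in 3, 4 and 4 of 5 cases in the first 3, and in each of these 4 of 5 libraries of the first group correlated best with their own number. That is a hint of a shared source from the data and not from the design, since titles end in cl1 to cl5 without saying whether cl stands for clutch. Not every pair passed 0.1, so the libraries were not paired. That rule does not exclude a shared source, so the blocked counts stand beside the main ones. A replicate block over all libraries gave 8989, 10317, 2595, 3765 and 896 calls, and within genotype 8860, 10282 and 901 for the arsenite comparisons and the difference of the responses. Blocking also brought the difference in the fall of as3mt past the threshold (edgeR adjusted p = 0.0485 and 0.0333), the unfolded protein response of mutants to a call by camera (adjusted p = 0.0429) and the stellate list of the genotypes without arsenite out of one (0.0509). It ended the calls of ctrb.2 and ctrl for genotype without arsenite (edgeR adjusted p = 0.0606 and 0.0852) and brought autophagy to a call for genotype with it (camera adjusted p = 0.0441). Thinning to the smallest total gave 8481, 9792, 2071, 3225 and 631, which says nothing about what more depth would add. Leaving out unexposed wild-type replicate 2 with exposed wild-type replicate 5 gave 8603 calls for arsenite in wild type and 778 for the difference of the responses.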

Other observations

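Markers of endothelial and stellate cells fell in exposed wild type relative to other genes, by camera at the preset correlation only. Of 25 endothelial markers, 20 fell and 1 rose, the same adjusted over the list alone, with kdrl at a log2 change of -1.13 ± 0.10 (SE, n = 5 per group) and a median of -0.83 (-0.10 scaled to total counts, camera adjusted p = 4.01e-06, and adjusted p = 0.0949 with an estimated correlation). Of 31 stellate cell and fibroblast markers, 17 fell and 2 rose in both counts, and their median of -0.54 turned to 0.19 scaled to total counts (camera adjusted p = 0.00339, and adjusted p = 0.151 with an estimated correlation). Macrophage markers fell in 10 and rose in 2 of 27 cases in both counts without a call for the list (median -0.87, -0.15 scaled to total counts, camera adjusted p = 0.15). Other cell types gave no call in wild type or mutants, with camera adjusted p from 0.101 for skin in mutants to 0.95 for brain in mutants. For skeletal muscle in wild type the median was 0.96 and the mean 1.2 while camera ranked the list down (adjusted p = 0.831), with exposed replicate 3 at a mean log2 CPM of 2.75, the other exposed libraries at -0.89 to 0.05 and the unexposed at a mean of 0.09. Only 1 endocrine pancreas gene was measured, and it differed by 4.09 with arsenite in wild type and 6.12 in mutants, which rests on 8 and 2 counts in the 5 unexposed libraries together.

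Stress lists without a call moved both ways. Of 47 integrated stress response genes, 21 rose and 13 fell in wild type (22 and 14 adjusted over the list alone) and 21 and 15 in mutants (21 and 17), with medians of 0.18 and 0.35 (camera adjusted p = 0.275 and 0.378). Of 39 hypoxia genes, 14 rose and 13 fell in wild type in both counts, with a median of -0.01, a mean of 0.45 and 0.73 as the median scaled to total counts (camera direction up, adjusted p = 0.831). Of 49 unfolded protein response genes in mutants, 8 rose and 23 fell in both counts, with a median of -0.56 that turned to 0.27 scaled to total counts (camera adjusted p = 0.0677). Camera called this list down with the pancreas covariate (adjusted p = 0.0423) and with the replicate block (0.0429), and not with an estimated correlation (0.833). Interferon genes rose in 13 and fell in 2 of 27 cases in mutants (11 and 2 adjusted over the list alone, median 1.06, camera adjusted p = 0.341) and were higher in unexposed mutants than in wild type in 5 cases (5 with 1 lower adjusted over the list alone, median 0.40, camera adjusted p = 0.137). Phase II conjugation genes fell in 27 and rose in 6 of 53 cases in wild type (27 and 7 adjusted over the list alone), with a median of -0.55 that turned to 0.15 scaled to total counts (camera adjusted p = 0.0984). Respiratory chain genes fell in 30 and rose in 5 of 95 cases in wild type (23 and 5 adjusted over the list alone), with a median of -0.17 that turned to 0.55 scaled to total counts (camera adjusted p = 0.0587).

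The 13 genes encoded on the mitochondrial genome took 5.62% ± 0.55 (SD, n = 5) of counts in unexposed and 5.45% ± 0.53 in exposed wild type, and 6.24% ± 0.29 and 6.33% ± 0.50 in mutants.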
